A study of Homo sapiens with 6 samples.

How the data were processed

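Cells labelled Huh7 were transfected with a TP53TG1 plasmid or an empty plasmid, with 3 replicates of each. Total RNA was extracted with TRIzol and treated with DNase I, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Whether polyadenylated RNA was selected, whether the libraries keep the strand, and the read length are not given in the sources used here. HISAT2 (an aligner), StringTie (a transcript assembler and quantifier) and the genome build GRCh38.p10 are named in the submitters' processing notes, and their versions and parameters and the annotation release are not given in the sources used here.

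The authors deposited 1 value per annotated transcript and library, with 2 decimals, and the file headers give no unit. The values were taken as FPKM (fragments per kilobase of transcript and 1000000 fragments), since they are not whole numbers and each deposited library sums to a different total, from 599081 to 890541, where TPM would sum to the same total. Coverage per base, which StringTie also writes and which is not divided by depth, is not excluded by these values. FPKM are already divided by length and depth but not by any factor that makes libraries comparable, so a library in which a few RNAs take a large share shows lower values for all others. The planned count tests did not apply to this unit and were not run. TPM was compared as FPKM rescaled to the same total per library.

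The values of all transcripts of a gene were added. Gene symbols were blank in 0 to 88000 rows of a library and were filled from the other libraries, which list the same transcripts in the same order. Biotypes, coordinates and transcript lengths came from GENCODE release 29 (GRCh38), in which 99.8% of the transcripts were found. The deposited tables give no coordinates. A gene's length was the mean over its transcripts weighted by their values. No 2 libraries held identical values. An exact 0 may be a failed estimate: 3 genes were at 0 in 1 library and at 10 FPKM or more in the other 5, so genes at 0 are described as listed at 0.

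Depth was read from the low values. In genes with a single transcript of 300 to 1500 nt, values were multiplied by length in kb. Values under a low cut in FPKM and products above a second cut were left out. Percentile 5 of the remaining products gave a step of 0.0503 to 0.0627 FPKM kb. The low cut can remove single fragments of the longer of these transcripts, and its effect on the step was not tested. If that step is 1 fragment, it corresponds to 15900000 to 19900000 fragments per library. This is an estimate and no interval was derived from it.

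Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with a mean-variance trend) in R 4.3.3, TP53TG1 minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which does not compare a list with the other genes. Tests of single genes without a model were exact two-sided permutation tests of 3 against 3 libraries. The tables were joined in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.

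The design, 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of 642 list entries 641 matched a gene, and 33 lists had at least 3 tested members. TP53TG1, its neighbour CROT, PRDX4 and CTNNB1 were always named. To these were added up to 10 genes per direction with the largest change among those past the threshold, with a symbol, a mean of at least 2 FPKM in the higher group and groups that did not overlap. Where fewer than 5 passed, the genes with the smallest p filled up to 5. From each list up to 4 members with the smallest p were named where they add to the account of the list. The result of 1 gene is not reported here.

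Both groups are numbered 1 to 3 in the labels, which do not say whether a number marks a shared day or culture. Deviations from the group means correlated across genes at 0.710, 0.562 and 0.289 between libraries numbered 1, 2 and 3, all above the limit of 0.1 set for calling them paired, and 4 of 6 libraries correlated best with their own number in the other group. Libraries of unlike number passed that limit too, at 0.400 for control replicate 3 with TP53TG1 replicate 2 and 0.302 for control replicate 2 with TP53TG1 replicate 3. Deviations cancel out within a group, and both libraries numbered 1 stand apart. Values above the limit thus do not by themselves show that replicates 2 and 3 pair by number. The pairing is taken from the data, and a fit with the replicate number as a block is given where it changes a call. That fit left 2 residual degrees of freedom, and its prior degrees of freedom were infinite, so that every gene's spread was read from the trend.

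The fits were tested on simulated data, with 12853 genes, 200 of them changed, and 3 runs. With the replicate effects of the real libraries, the fit without a block called 0% of 2-fold and 9% of 4-fold changes, and the fit with the block 73.3% and 94.3%, with 14 false calls on average. Without replicate effects the fit without a block called 69.3% and 97.7%. The simulated spread was taken from the fit with block and median-of-ratios scaling. The real fit with the block alone had a larger SE, such as 0.306 against 0.138 for PRDX4. In that real fit AMBP, at a log2 fold change of -0.97, had a limma adjusted p of 0.150. The shares recovered with the block thus do not describe the block fit of the real libraries. A list of genes all raised 2-fold was called in 3 of 3 runs and an unshifted list in 0. Apart from the replicate effects, noise was drawn for each gene separately. These runs therefore do not test how camera with a preset correlation treats genes that vary together.

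Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, a robust variance model, the replicate block, protein-coding genes, values rescaled after leaving out mitochondrial and the 20 most abundant genes, a change of at least 2-fold beside the threshold, and each library left out in turn. Values rescaled to the same total per library, the block together with a scaling, and leaving out both libraries numbered 1 were added after seeing the data.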

Results

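Gene expression was measured by RNA sequencing in 6 libraries of cells labelled Huh7, a human hepatocellular carcinoma cell line. In 3 libraries the cells carried a plasmid for TP53TG1, a long noncoding RNA gene first described as a gene induced by p53, and in the other 3 an empty plasmid (control). Each library listed FPKM values for 199234 transcripts of 58233 genes, and the 12853 genes with a mean of at least 1 FPKM were tested. The FPKM of a library summed to between 599081 in TP53TG1 replicate 1 and 890541 in control replicate 1. Read counts were not analysed here. If the step read from low FPKM values, after a cut on the lowest, is taken as 1 fragment, the libraries held 15900000 to 19900000 fragments. A value of 1 FPKM for a transcript of 1500 nt would then rest on 23.9 to 29.8 fragments. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

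Transcripts that hepatocytes secrete in large amounts were low in all 6 libraries. ALB, which encodes serum albumin, lay between 0.53 and 1.22 FPKM, and AFP, the fetal liver protein used as a marker of hepatocellular carcinoma, between 0.63 and 3.49 FPKM. Of 16 hepatocyte secreted protein genes, 5 reached a mean of 1 FPKM over the 6 libraries. Among 15 hepatocyte transcription factor genes, 9 did, and HNF4A lay between 2.57 and 15.0 FPKM. Of 14 genes listed as markers of epithelial cell lines from other tissues, 2 reached a mean of 1 FPKM. These were CDKN2A, a cell cycle inhibitor gene, at 82.0 to 332 FPKM, and CDX2, an intestinal transcription factor gene, at 4.71 to 10.2 FPKM. KRT20, an intestinal keratin gene chosen after its values were seen, lay between 51.1 and 171 FPKM. No expression profile of Huh7 from elsewhere was used here, so the identity of the line was not tested.

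TP53TG1, the transfected gene, averaged 91.5 ± 37.0 FPKM (SD, n = 3) in the TP53TG1 libraries against 7.32 ± 2.85 FPKM (SD, n = 3) in the controls, a ratio of means of 12.5. The values were 69.8, 134 and 70.5 FPKM with the plasmid and 10.6, 5.25 and 6.15 FPKM in controls 1, 2 and 3, so the groups did not overlap. Between libraries of the same number the ratios were 6.61, 25.6 and 11.5. The gene is annotated as a long intergenic noncoding RNA on chromosome 7, 87325225 to 87345515 (GRCh38). The log2 fold change on the log2(FPKM + 1) scale was 3.46 (SE 0.381), with an adjusted p of 0.0573 by limma with Benjamini-Hochberg adjustment, above the 0.05 threshold. With the replicate number as a block the adjusted p was 8.97e-22, and 0.00818 when median-of-ratios scaling was added. Over all alternatives it ran from 8.97e-22 to 0.799. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

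Of the 7 transcripts listed for TP53TG1, 5 had a value above 0 in at least 1 library. ENST00000359941, of 855 nt, held 75.5 ± 5.13% (SD, n = 3) of the gene's FPKM in the controls and 91.6 ± 1.45% (SD, n = 3) in the TP53TG1 libraries. ENST00000421293, of 439 nt, held 17.5 ± 4.44% and 6.59 ± 1.54% (SD, n = 3 each). The labels do not say which transcript the plasmid carries.

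**Figure D1:**
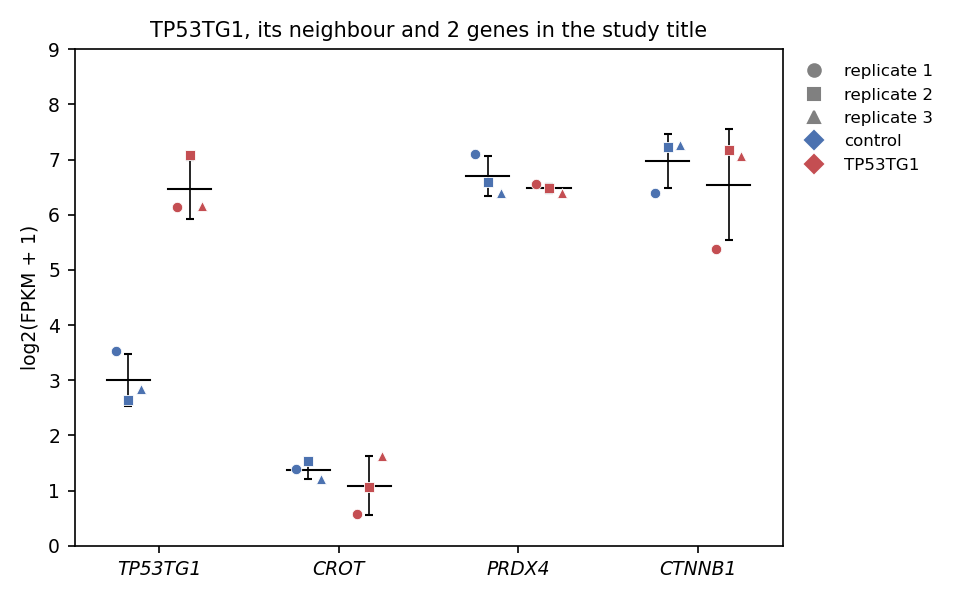
Expression of TP53TG1, CROT, PRDX4 and CTNNB1 as log2(FPKM + 1) in the 6 libraries, with the replicate number as the marker shape, the group as the colour, and mean ± SD (n = 3) in black. For TP53TG1 the 3 TP53TG1 libraries (69.8 to 134 FPKM) lie above the 3 controls (5.25 to 10.6 FPKM), and for the other 3 genes the groups overlap.

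PRDX4 and CTNNB1 are the genes the study's title connects with TP53TG1, and neither passed the test. The values are RNA levels, which do not show the amount, stability or location of the proteins. PRDX4, an endoplasmic reticulum peroxiredoxin gene (chromosome X, 23664262 to 23686399), averaged 105 ± 27.4 FPKM in the controls and 88.1 ± 4.66 FPKM in the TP53TG1 libraries (SD, n = 3 each). Its log2 fold change was -0.23 (SE 0.269, limma with Benjamini-Hochberg adjusted p = 0.748) and turned to 0.17 with median-of-ratios scaling. CTNNB1, which encodes beta-catenin (chromosome 3, 41194741 to 41260096), averaged 128 ± 39.0 FPKM in the controls and 106 ± 56.7 FPKM in the TP53TG1 libraries (SD, n = 3 each). Its log2 fold change was -0.42 (SE 0.490, adjusted p = 0.748), -0.03 with median-of-ratios scaling, and 0.16 without TP53TG1 replicate 1. Without scaling, the median log2 fold change of all tested genes was -0.35. CROT, a peroxisomal carnitine octanoyltransferase gene next to TP53TG1 (chromosome 7, 87345681 to 87399795), stood at 1.60 ± 0.295 FPKM in the controls and 1.22 ± 0.813 FPKM in the TP53TG1 libraries (SD, n = 3 each). In exact two-sided permutation tests PRDX4 gave p = 0.4 and CTNNB1 and CROT p = 0.5 each, where 0.1 is the smallest possible. These tests exchange libraries freely and do not use the pairing by number. From pair 1 to 3 the ratio of TP53TG1 to control was 0.49, 0.97 and 0.87 for CTNNB1 and 0.68, 0.92 and 1.00 for PRDX4, and neither passed with the block (adjusted p = 0.523 and 0.637). These ratios are of unscaled FPKM and include the scale of the libraries. The median-of-ratios factors were 0.621, 1.077 and 1.001 in TP53TG1 replicates 1 to 3 and 1.127, 1.165 and 1.160 in the controls.

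The libraries numbered 1 differed from the others more than the groups did. The first principal component held 62.5% of the variance and gave scores of -30.6 to control replicate 1 and -97.2 to TP53TG1 replicate 1, against 14.6 to 42.1 for the other 4 libraries. Across genes, Pearson correlations of log2(FPKM + 1) were 0.952 to 0.975 between libraries of the same number and 0.886 to 0.972 within a group. Small structured RNA genes held 0.777% of all FPKM in control replicate 1 and 6.59% in TP53TG1 replicate 1, against 0.249% to 1.52% in the other 4. Mitochondrial mRNAs held 14.6% and 13.3% in the libraries numbered 1 and 10.3% to 11.5% in the others. The weighted mean transcript length of protein-coding genes was 1351 nt and 1286 nt in the libraries numbered 1, against 1622 to 1665 nt.

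**Figure D2:**
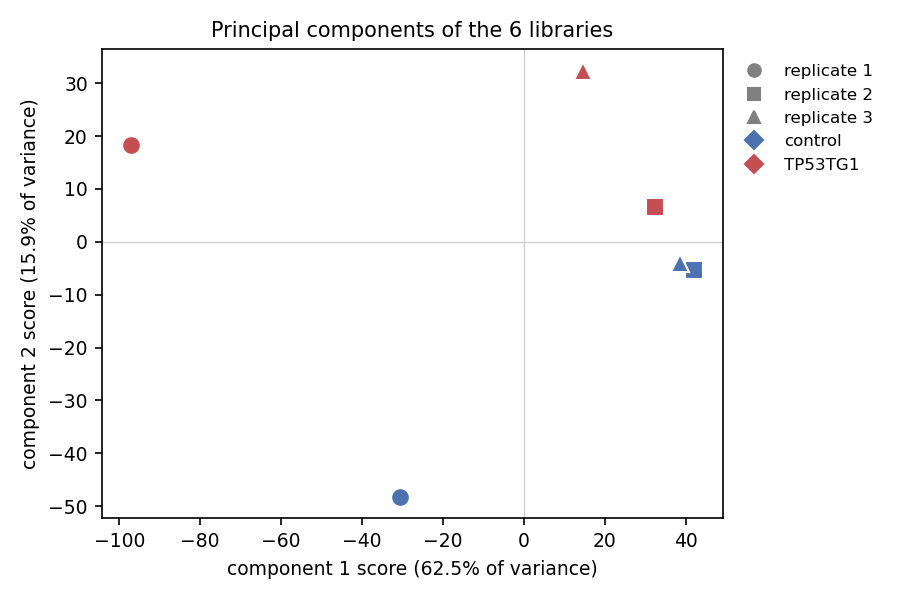
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 12853 genes, with the percent of variance on each axis, the group as colour and the replicate number as shape. Component 1 places the libraries numbered 1 (-30.6 and -97.2) apart from the other 4 (14.6 to 42.1).

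A single gene passed the test of TP53TG1 against control. TTC28-AS1_2, a 157 nt RNA (chromosome 22, 27922022 to 27922178, plus strand), was listed at 0 in the 3 controls and at 61.3, 29.4 and 39.6 FPKM in the TP53TG1 libraries (limma with Benjamini-Hochberg adjusted p = 0.00229). It lies inside the antisense RNA gene TTC28-AS1 on the same strand and overlaps exons of 5 of its 21 transcripts, so fragments of the 2 genes may not be separable. TTC28-AS1 itself stood at 4.70 ± 0.621 and 5.29 ± 1.28 FPKM (SD, n = 3 each). The call of TTC28-AS1_2 was lost without control replicate 1 (adjusted p = 0.0784) and with no filter on low values (0.0727). At an unadjusted p under 0.05 there were 302 genes, 56 higher and 246 lower. The median log2 fold change of all tested genes was -0.35, and -0.01 with median-of-ratios scaling, which gave 92 higher and 56 lower. Changes of gene groups are therefore given relative to the median of all tested genes. Groups did not overlap for 55 genes higher and 1705 lower, 0.43% and 13.3% of those tested, where chance gives 10% for both directions together if any 3 libraries can be exchanged for the others. Libraries that pair by number, as those numbered 1 do, do not meet that condition, so 10% is not a reference for these shares. With median-of-ratios scaling it was 260 higher and 269 lower, 4.13%.

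With the replicate number as a block, 192 genes passed, 75 higher and 117 lower. In that fit the estimated spread followed the mean-variance trend alone, and 98 of the 192 genes had a value of 0 in at least 1 library. With median-of-ratios scaling added, 7 genes passed, all of them higher with TP53TG1: TP53TG1, TTC28-AS1_2, LCN2, DKK1, RMRP, RPPH1 and RN7SL3. Rescaling each library to the same total in place of that gave 9, with RN7SL1 and RN7SK in addition. Without the libraries numbered 1, the fit with no block called 1 gene, TTC28-AS1_2.

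LCN2, which encodes the iron-siderophore binding protein lipocalin 2 (chromosome 9, 128149071 to 128153455), was at 812, 375 and 422 FPKM in TP53TG1 replicates 1 to 3 and at 193, 36.7 and 69.2 FPKM in the controls. Its log2 fold change was 2.66 (SE 0.562), with an adjusted p of 0.748 without the block, 1.22e-17 with it and 0.00558 with block and median-of-ratios scaling (limma, Benjamini-Hochberg). PDZK1IP1, a membrane protein gene, stood at 23.8 ± 19.6 FPKM with TP53TG1 and 1.89 ± 1.52 FPKM in the controls, and SAA1, an acute phase apolipoprotein gene, at 5.59 ± 5.18 and 0.077 ± 0.067 FPKM (SD, n = 3 each). On the lower side, AKR1B10, an aldo-keto reductase gene, averaged 972 ± 114 FPKM with TP53TG1 and 1880 ± 218 FPKM in the controls (SD, n = 3 each). Its log2 fold change was -0.95 (SE 0.223), and -0.56 with median-of-ratios scaling. Means in FPKM are not scaled between libraries, so lower genes include the general shift of -0.35. PLA2G12A, a secreted phospholipase gene, stood at 7.02 ± 0.898 against 25.5 ± 8.86 FPKM, and RINL at 4.84 ± 1.76 against 16.1 ± 2.07 FPKM (SD, n = 3 each). TDGF1, an EGF-CFC growth factor gene, stood at 0.297 ± 0.275 against 2.30 ± 0.481 FPKM, and TMED6 at 0.490 ± 0.139 against 2.88 ± 0.925 FPKM (SD, n = 3 each). All of these were named by their small p and did not pass without the block (adjusted p = 0.748). Apart from LCN2 they passed with it (adjusted p from 3.51e-15 for PDZK1IP1 to 0.00553 for TMED6), and did not pass with block and median-of-ratios scaling.

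Among 33 gene lists with at least 3 tested members, 17 moved relative to the other genes by camera with a preset correlation of 0.01, 13 higher and 4 lower. The 13 include the list that holds the transfected gene itself. None of the 17 held with an estimated correlation (lowest adjusted p = 0.124), and none of the 33 passed by fry. No member of any list passed when adjusted over all genes, and 5 did when adjusted over the list alone: LCN2, SAA1, C3, AKR1B10 and TP53TG1. Without the libraries numbered 1, 16 lists passed.

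Inflammation genes were higher with TP53TG1 relative to the other genes. All 15 tested genes of the NF-kB and acute inflammation list lay above the median of all genes, the list median by 0.76 on the log2 scale (0.31 to 1.04 over settings, lowest with no filter; camera adjusted p = 6.02e-20). Its adjusted p was 0.183 with an estimated correlation. No member passed over all genes, and LCN2 did when adjusted over the list alone. CCL20, a chemokine gene, stood at 23.4 ± 26.6 FPKM with TP53TG1 and 4.70 ± 0.709 FPKM in the controls (SD, n = 3 each), and passed with the replicate block (adjusted p = 0.000856). BIRC3, an inhibitor of apoptosis gene induced by NF-kB, averaged 15.3 ± 7.72 against 8.66 ± 2.78 FPKM, and the chemokine gene CXCL1 14.9 ± 10.8 against 7.26 ± 1.90 FPKM (SD, n = 3 each). CXCL1 and CCL20 were highest in TP53TG1 replicate 2, at 27.3 and 54.1 FPKM. In the libraries numbered 1, unscaled FPKM of CXCL1 and BIRC3 were lower with TP53TG1 (7.37 against 9.44 and 9.72 against 11.8 FPKM). The median-of-ratios factors of these libraries differed by more, at 0.621 with TP53TG1 and 1.127 in the control. Relative to other genes, the 2 genes were thus not lower in that pair. The acute phase protein list, with 7 of 16 genes tested, lay 0.55 above the median of all genes (camera adjusted p = 4.36e-11). With an estimated correlation its adjusted p was 0.134, and its call was lost when only genes with a mean of at least 5 were tested (adjusted p = 0.0588, list median -0.18). SAA1 and C3 passed when adjusted over the list alone. C3, the central complement component gene, was at 3.46 ± 1.69 against 0.620 ± 0.066 FPKM (SD, n = 3 each), and passed with the block (adjusted p = 0.00360). CP, the ceruloplasmin gene, was at 78.7 ± 34.6 against 43.4 ± 6.92 FPKM, and the fibrinogen gene FGB at 14.9 ± 7.60 against 20.8 ± 6.76 FPKM (SD, n = 3 each).

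Small structured RNAs transcribed by RNA polymerase III led the list of nuclear retained and structured RNA, of which 6 of 10 tested genes lay above the median of all genes. The list median lay 0.94 above that median (0.15 to 1.68 over settings, lowest with no filter; camera adjusted p = 1.64e-09), with an adjusted p of 0.243 with an estimated correlation and 0.154 without TP53TG1 replicate 1. RMRP, the RNA of RNase MRP, was at 1144, 223 and 331 FPKM in TP53TG1 replicates 1 to 3 and at 297, 25.7 and 46.5 FPKM in the controls. A second gene of the same symbol at the same place was listed at 60.0 FPKM in TP53TG1 replicate 1 and at 0 elsewhere, and is not part of these values. The log2 fold change of RMRP was 2.61 (SE 0.880), with a limma and Benjamini-Hochberg adjusted p of 2.00e-16 with the block and 0.00333 with block and median-of-ratios scaling. RPPH1, the RNA of RNase P, had a log2 fold change of 3.64 (SE 1.24), and passed in the same fits (adjusted p = 3.88e-27 and 0.00278). RN7SK was at 555 ± 640 against 88.1 ± 85.4 FPKM, and RN7SL1, the signal recognition particle RNA, at 3561 ± 3752 against 994 ± 1017 FPKM (SD, n = 3 each). Both passed with the block alone (adjusted p = 1.93e-13 and 9.61e-14), and not when median-of-ratios scaling was added (0.0776 and 0.153). The share of such RNAs in all FPKM was also the measure in which TP53TG1 replicate 1 stood out, at 6.59%.

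**Figure D3:**
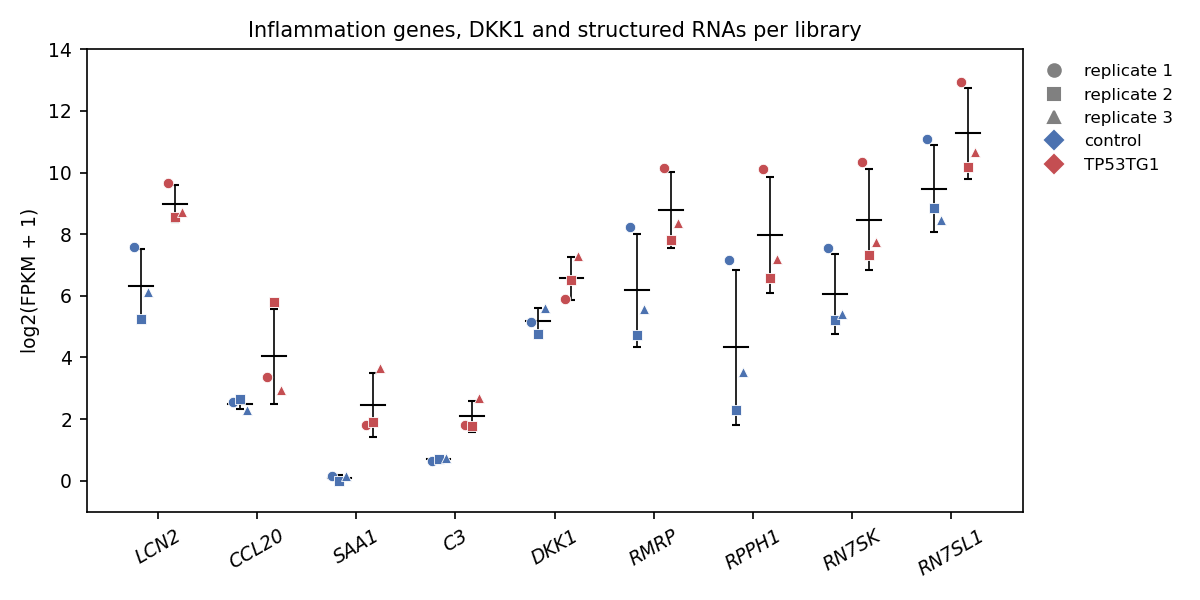
Expression of 9 genes as log2(FPKM + 1) in the 6 libraries, with replicate number as shape, group as colour and mean ± SD (n = 3) in black. In each of the 3 pairs of the same number, the TP53TG1 library lies above its control for every gene shown, and RMRP spans 25.7 to 297 FPKM in the controls and 223 to 1144 FPKM with TP53TG1. Members of the same lists that are not shown include CXCL1, BIRC3 and CP, lower with TP53TG1 in the pair numbered 1, and FGB, lower in all 3 pairs. All of these comparisons are of FPKM without scaling between libraries.

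Genes of 2 stress pathways lay lower than the other genes with TP53TG1, by camera with the preset correlation only. In the list of NRF2 target genes, 18 of 20 lay below the median of all genes, the list median by -0.35 (camera adjusted p = 4.43e-08, and adjusted p = 0.308 with an estimated correlation). AKR1B10 passed when adjusted over the list alone. AKR1C2, a steroid-metabolising aldo-keto reductase gene, averaged 96.4 ± 60.7 against 203 ± 19.4 FPKM (SD, n = 3 each) and passed with the block (adjusted p = 0.00209). The quinone reductase gene NQO1 averaged 470 ± 64.3 against 769 ± 191 FPKM (SD, n = 3 each). Its log2 fold change was -0.69, and -0.29 with median-of-ratios scaling. In the integrated stress response list all 20 tested genes lay below the median of all genes, the list median by -0.53 (camera adjusted p = 1.09e-06). Its adjusted p was 0.589 with an estimated correlation, and without TP53TG1 replicate 3 it was 0.438 at a list median of -0.05. No member passed over all genes or over the list alone, and 8 passed with the block, all lower, of which 0 passed when median-of-ratios scaling was added. TRIB3, a pseudokinase gene induced by ATF4, was at 5.23, 15.1 and 3.24 FPKM in TP53TG1 replicates 1 to 3 and at 15.3, 24.9 and 51.2 FPKM in the controls. The transcription factor gene ATF4 averaged 250 ± 136 against 450 ± 48.3 FPKM, DDIT4 145 ± 98.2 against 288 ± 39.8 FPKM, and the serine synthesis gene PSAT1 198 ± 107 against 331 ± 55.9 FPKM (SD, n = 3 each). The lowest values of ATF4, DDIT4 and PSAT1 were all in TP53TG1 replicate 3, at 103, 35.3 and 108 FPKM.

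**Figure D4:**
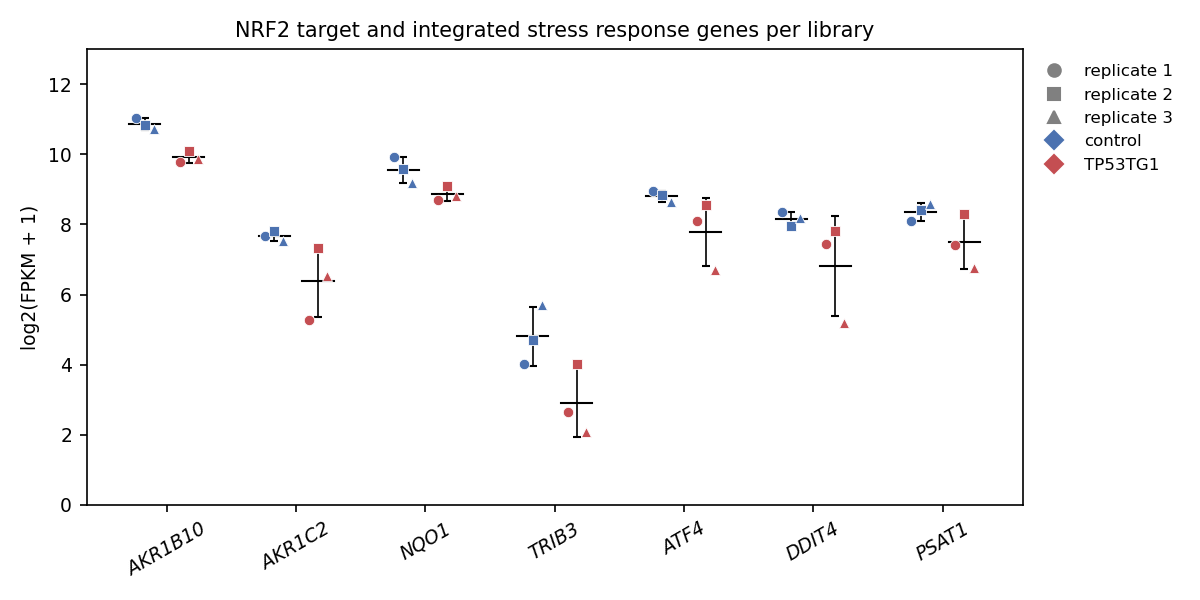
Expression of 3 NRF2 target genes and 4 integrated stress response genes as log2(FPKM + 1) in the 6 libraries, with replicate number as shape, group as colour and mean ± SD (n = 3) in black. AKR1B10 lies at 885 to 1101 FPKM with TP53TG1 and 1684 to 2114 FPKM in the controls, while DDIT4 is lowest in TP53TG1 replicate 3 at 35.3 FPKM.

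Wnt/beta-catenin target genes went both ways. DKK1, a secreted Wnt antagonist gene (chromosome 10, 52314296 to 52318042), averaged 102 ± 50.4 FPKM with TP53TG1 and 36.3 ± 10.9 FPKM in the controls (SD, n = 3 each). Its log2 fold change was 1.38 (SE 0.401), with a limma and Benjamini-Hochberg adjusted p of 0.748, of 0.00189 with the block and of 0.0312 with block and median-of-ratios scaling. MYC averaged 90.7 ± 42.8 against 171 ± 37.9 FPKM and the matrix metalloprotease gene MMP7 17.1 ± 7.21 against 9.58 ± 1.47 FPKM (SD, n = 3 each). The list median lay 0.12 above that of all genes (14 tested, 10 above), with a camera adjusted p of 0.000608 and an adjusted p of 0.611 with an estimated correlation. The call was lost without control replicate 1 (adjusted p = 0.104, list median -0.06), without TP53TG1 replicate 3 (0.274, list median -0.08) and with no filter on low values (0.0657, list median 0.05). Components of the Wnt/beta-catenin pathway lay -0.10 from the median (20 tested, camera adjusted p = 0.0675). They passed as lower in 8 of 22 settings, among them median-of-ratios scaling (0.0324), that scaling with the block (0.0388) and no filter (0.0179). WNT5A was at 0.847 ± 0.619 against 2.73 ± 1.45 FPKM and AXIN1 at 17.5 ± 6.73 against 29.9 ± 5.66 FPKM (SD, n = 3 each). The peroxiredoxin and thioredoxin list did not pass (16 tested, adjusted p = 0.999).

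Genes of the mesenchyme and its matrix were higher relative to the other genes. The mesenchymal and invasion list had 19 of 23 genes above the median of all genes, the list median by 0.33 (camera adjusted p = 1.09e-06, and adjusted p = 0.413 with an estimated correlation). TGFBI, a matrix protein gene, averaged 53.1 ± 9.02 against 40.3 ± 2.85 FPKM, the matrix protein gene SPARC 6.18 ± 4.90 against 2.97 ± 1.55 FPKM, and the fibronectin gene FN1 333 ± 92.0 against 458 ± 153 FPKM (SD, n = 3 each). Markers of fibroblasts and stellate cells had 7 of 8 tested genes above the median, the list median by 0.82 (camera adjusted p = 2.24e-11, and adjusted p = 0.124 with an estimated correlation). Their levels were low, with the collagen gene COL1A1 at 5.71 ± 4.48 against 2.48 ± 0.584 FPKM and TAGLN at 4.67 ± 0.422 against 3.07 ± 0.595 FPKM (SD, n = 3 each). COL1A1 and SPARC were highest in TP53TG1 replicate 1, at 10.9 and 11.8 FPKM against 3.05 to 3.43 FPKM in the other 2 TP53TG1 libraries. The list median fell to 0.34 without that library and to 0.44 without both libraries numbered 1 (adjusted p = 0.000482 for the latter), and the list passed in both. Epithelial junction genes (13 tested, adjusted p = 0.479), endothelial markers (3, adjusted p = 0.681) and cholangiocyte and progenitor markers (4, adjusted p = 0.699) did not pass. Leukocyte markers had 2 tested genes, CD68 and CD14, and were tested as a list only in settings that kept more of them. They passed as higher in all 4 of these, with no filter on low values at a list median of 0.20 (13 tested, camera adjusted p = 0.000191). In that setting the median log2 fold change of all genes was -0.13, and 12 of the 14 markers had a mean below 1 FPKM. Genes near 0 change little on the log2(FPKM + 1) scale, so they lie above a negative median without a rise of their own.

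Other lists moved by less than 0.3 relative to the median of all genes. Interferon response genes lay 0.27 above it (13 of 14 above, camera adjusted p = 9.44e-05, and adjusted p = 0.413 with an estimated correlation), a call lost without control replicate 3 (0.153), without TP53TG1 replicate 1 (0.0559) and with no filter on low values (0.126, list median 0.07). DNA replication genes lay 0.29 above it (23 of 25 above, camera adjusted p = 0.000232, and adjusted p = 0.817 with an estimated correlation). Without TP53TG1 replicate 3 their median was -0.05 (adjusted p = 0.670), and without control replicate 1 (0.173) and with no filter (0.255, list median 0.07) the call was lost as well. Hypoxia and glycolysis genes lay 0.23 above it (19 of 22 above, camera adjusted p = 0.000955, and adjusted p = 0.611 with an estimated correlation), a call lost without control replicate 2 (0.165), without TP53TG1 replicate 2 (0.0820) and with no filter (0.345, list median 0.01). VEGFA, the angiogenic growth factor gene, was at 65.7 ± 31.2 against 107 ± 27.1 FPKM (SD, n = 3 each), a log2 fold change of -0.77, and of -0.38 with median-of-ratios scaling. The list of the transfected gene and its neighbour passed (camera adjusted p = 0.000391, and adjusted p = 0.198 with an estimated correlation), at a list median 0.06 above that of all genes. TP53TG1 was the only one of its 3 members to pass when adjusted over the list alone. The rise of this list follows from the transfection and is not a separate result. The call was lost with no filter (0.102) and with block and median-of-ratios scaling (0.106).

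For 5 further lists the call was lost with the replicate block. Replication-dependent histone genes lay 0.26 above the median (6 of 7 above, camera adjusted p = 0.00650, with the block 0.339, and adjusted p = 0.413 with an estimated correlation). HIST1H2BK went the other way, at 7.96 ± 7.08 against 35.7 ± 24.7 FPKM (SD, n = 3 each), and the list lost its call without TP53TG1 replicate 1 (0.912), without control replicate 2 (0.261), with a mean of at least 5 (0.405), with median-of-ratios scaling (0.0959), with quantile normalization (0.0894) and without both libraries numbered 1 (0.0547). Heat shock protein genes lay 0.21 above it (13 of 14 above, camera adjusted p = 0.00778, with the block 0.0640, and adjusted p = 0.611 with an estimated correlation). Without TP53TG1 replicate 3 their median was -0.06 (0.404), and without control replicate 3 the call was lost too (0.243). Cholesterol synthesis genes lay 0.17 above it (15 of 21 above, camera adjusted p = 0.0141, with the block 0.144, and adjusted p = 0.819 with an estimated correlation). That call was lost without control replicate 1 (0.336), control replicate 3 (0.309), TP53TG1 replicate 2 (0.118) or TP53TG1 replicate 3 (0.635, list median -0.12). Fatty acid synthesis and oxidation genes lay below it (15 of 18 below, list median -0.19, camera adjusted p = 0.0229, with the block 0.0640, and adjusted p = 0.819 with an estimated correlation). That call was lost without control replicate 1 (0.0535), control replicate 2 (0.215), TP53TG1 replicate 1 (0.478) or both libraries numbered 1 (0.272), and with a mean of at least 5 (0.104). Hepatocyte transcription factor genes lay below it (7 of 9 below, list median -0.27, camera adjusted p = 0.0481, with the block 0.113, and adjusted p = 0.611 with an estimated correlation), and lost their call without any library but TP53TG1 replicate 2. The adjusted p was 0.150, 0.0853 and 0.0840 without control replicates 1, 2 and 3, 0.154 without TP53TG1 replicate 1 and 0.183 without TP53TG1 replicate 3. Among them CEBPB was at 56.8 ± 21.8 against 105 ± 11.0 FPKM and FOXA2 at 19.7 ± 7.83 against 32.7 ± 6.45 FPKM (SD, n = 3 each).

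The remaining lists did not pass in the fit without a block, and some passed in other settings. Ribosomal protein genes had a list median of 0.01 and a mean of -0.003 relative to all genes (28 tested, camera adjusted p = 0.0517, direction lower), and pointed higher with median-of-ratios scaling (0.415). They passed as lower in 9 of 22 settings, among them the block (0.0224), no filter (0.0302), leaving out both libraries numbered 1 (5.97e-06), control replicate 2 (4.70e-05) or TP53TG1 replicate 1 (3.21e-06). Cell cycle and mitosis genes had an adjusted p of 0.0576 (25 tested; passed as higher in 4 of 22 settings), nuclear oxidative phosphorylation genes 0.0816 (21 tested; passed as lower in 3 of 22) and hepatocyte secreted protein genes 0.0875 (5 tested; passed as lower in 2 of 21). The unfolded protein response list had an adjusted p of 0.108 (18 tested; passed as higher in 8 of 22) and apoptosis regulators 0.337 (18 tested; passed as higher in 4 of 22). For p53 target genes it was 0.479 (22 tested) and for immediate early genes 0.703 (15 tested). Mitochondrially encoded genes had 0.703 (13 tested) and passed in 5 of 21 settings, 4 as higher and 1 as lower. TGF-beta and SMAD targets had 0.911 (14 tested) and bile acid and xenobiotic metabolism genes 0.986 (8 tested).

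**Figure D5:**
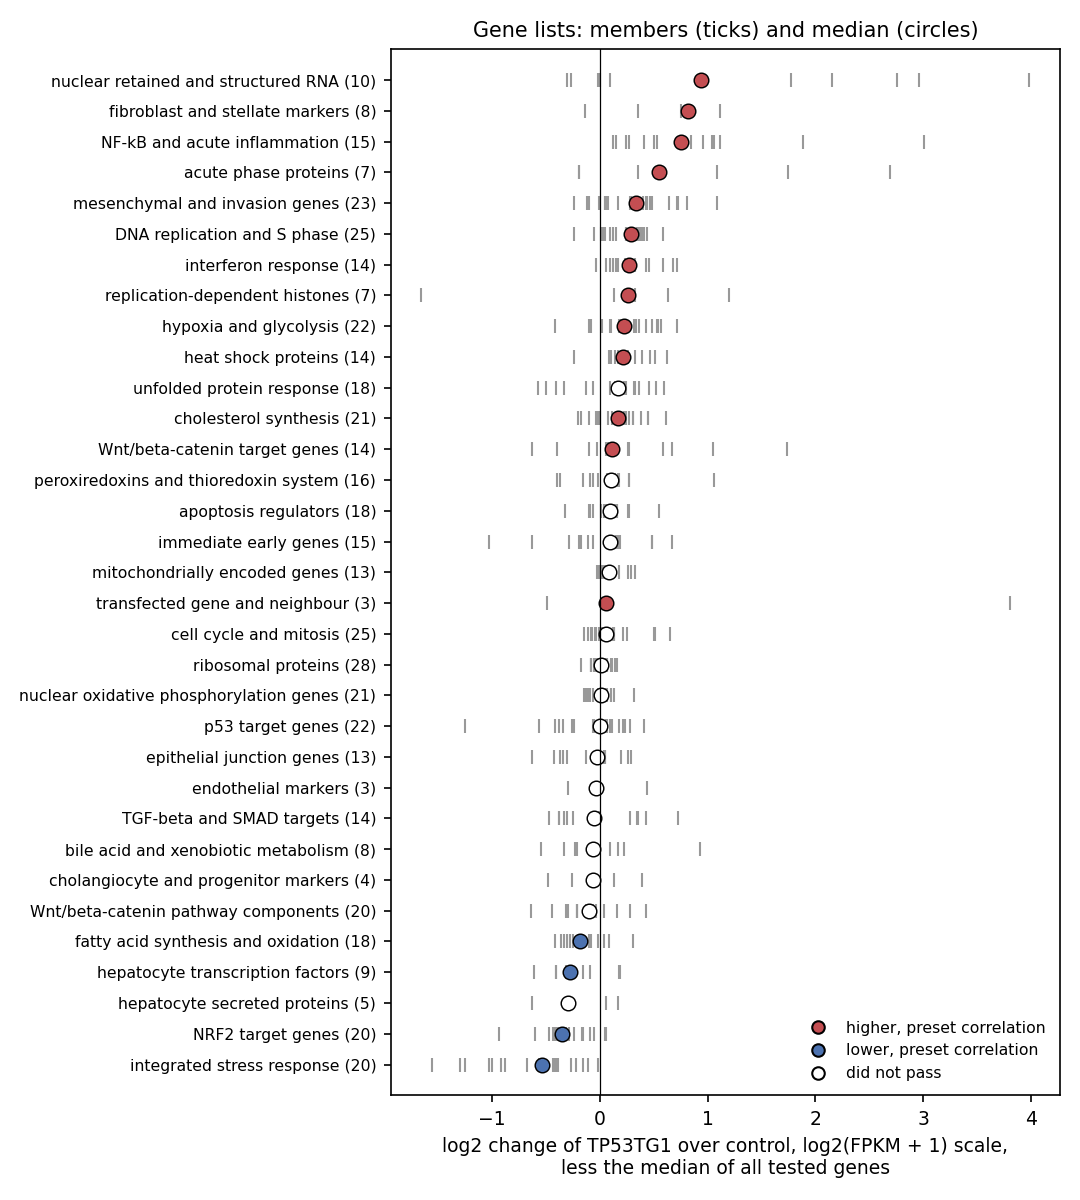
Log2 change of TP53TG1 over control on the log2(FPKM + 1) scale, less the median of all 12853 tested genes, for 33 gene lists with the number of tested members in parentheses. Ticks are members, circles are list medians, and a filled circle marks 1 of the 17 lists that passed camera with a preset correlation of 0.01; none passed with an estimated correlation.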

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

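Rescaling to the same total, the replicate block joined with a scaling, and leaving out both libraries numbered 1 were chosen after the data were seen. The count-based alternatives were not run, because the values are not counts. TPM was tried as FPKM rescaled to the same total. With 3 libraries per group and the replicate effects seen here, the self-test recovered 0% of 2-fold changes without the block, so a change that did not pass is not shown to be absent. Where a result changed, the cause was not tested unless stated.

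The count of changed genes, 1, was 0 with no filter, with protein-coding genes only (TTC28-AS1_2 is not one) and in 1 of the leave-one-out fits (0 to 1). It was 2 with a mean of at least 5, with median-of-ratios scaling and without mitochondrial and the 20 most abundant genes. With the replicate block it was 192, with block and median-of-ratios scaling 7, and with block and values rescaled to the same total 9. TP53TG1 passed with a mean of at least 5 (log2 fold change 3.46), median-of-ratios scaling (3.82), the replicate block (3.46), without mitochondrial and the 20 most abundant genes (3.75), block and median-of-ratios scaling (3.82) and block and rescaling (3.77). With each library left out in turn it ranged from 3.15 to 3.72 and did not pass (adjusted p 0.0951 to 0.303).

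The count of changed lists, 17, was 0 with an estimated correlation and 0 by fry, 13 with the replicate block, of which 12 were among the 17 with the same direction, and 11 to 17 with each library left out, 11 without TP53TG1 replicate 3. It was 13 with no filter, 12 with a mean of at least 5, 20 with median-of-ratios scaling and 21 without mitochondrial and the 20 most abundant genes. No filter lost 8 calls: interferon, DNA replication, hypoxia, Wnt targets, heat shock, cholesterol, hepatocyte transcription factors and the transfected gene and neighbour. It gained nuclear oxidative phosphorylation (0.00508), ribosomal (0.0302) and Wnt pathway component lists (0.0179), all lower, and leukocyte markers (0.000191), higher, which had too few tested genes at a mean of at least 1. NF-kB, NRF2, mesenchymal and fibroblast lists passed under each setting with a preset correlation in which they had members. Without TP53TG1 replicate 3 the direction reversed for cholesterol synthesis (-0.12), DNA replication (-0.048) and heat shock (-0.064), whose highest values, 0.474, 0.485 and 0.424, came without TP53TG1 replicate 1. Histones reversed without TP53TG1 replicate 1 (0.067, direction lower; highest 0.611 without control replicate 1). Mitochondrially encoded genes reversed without control replicate 3 (-0.087; from -0.235 without TP53TG1 replicate 1 to 0.393 without control replicate 1). With median-of-ratios scaling the unfolded protein response (adjusted p = 0.0156) and apoptosis lists (0.0314) passed as higher and the hepatocyte secreted list (0.0156) as lower. Of signs not past the threshold, 103 of genes and 51 of lists turned. The block changed no other list calls than those given. The first component held 51.1% to 72.3% of the variance with a library left out.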

Other observations

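The genes of the next 2 paragraphs were chosen after their values were seen, and so were the tests of length, of fragment number and of carry-over.

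Further secreted and membrane protein genes had higher values in the TP53TG1 library of every pair without passing the test (limma with Benjamini-Hochberg adjusted p = 0.748 each). VNN1, which encodes a pantetheinase, averaged 52.1 ± 28.0 FPKM with TP53TG1 and 14.6 ± 1.57 FPKM in the controls (SD, n = 3 each). C1S and C1R, the serine protease genes of the first complement component, averaged 29.2 ± 16.7 against 9.54 ± 1.92 FPKM and 20.2 ± 9.73 against 7.04 ± 3.75 FPKM (SD, n = 3 each). The complement factor B gene CFB averaged 2.61 ± 1.43 against 0.753 ± 0.131 FPKM, and TMEM158 26.0 ± 10.5 against 10.2 ± 4.18 FPKM (SD, n = 3 each). GSTA1, a glutathione transferase gene, went the other way in every pair, at 6.77 ± 2.12 against 24.1 ± 17.6 FPKM (SD, n = 3 each). With the replicate block VNN1, C1S, C1R, TMEM158 and GSTA1 passed and CFB did not (adjusted p = 0.156), and none passed when median-of-ratios scaling was added (adjusted p from 0.244 for TMEM158 to 0.667 for CFB).

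Intestinal epithelial genes outside the lists were measured in these libraries labelled Huh7. LGALS4 lay between 3.21 and 135 FPKM, the cadherin gene CDH17 between 6.85 and 33.7 FPKM and CEACAM5 between 1.59 and 9.69 FPKM, while GPC3, an oncofetal glypican gene often used as a marker of hepatocellular carcinoma, lay between 0.03 and 0.17 FPKM.

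The libraries numbered 1 stand apart in both groups. Fewer fragments in both are argued against only by the estimated value of 1 fragment, which was read after a cut on the lowest values. It was 0.0503 FPKM kb in control replicate 1, below that of control replicates 2 and 3 (0.0543 and 0.0529). In TP53TG1 replicate 1 that value was 0.0627, the highest of the 6 libraries. It also had the fewest transcripts above 0, 54565 against 68481 to 76835, so fewer fragments remain possible for that library. Across 6264 protein-coding genes, the deviation of the library numbered 1 from the rest of its group fell with transcript length (Spearman rho -0.635 in the controls and -0.632 in the TP53TG1 group; genes are not independent replicates). Between replicates 2 and 3 the same rho was -0.054 and 0.168. Lower values of long transcripts in these libraries, as partly degraded RNA or a different fragment size could give, is thus a candidate explanation, which the labels do not allow to be told from a separate culture or day.

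RMRP, RPPH1, RN7SK and RN7SL1 are higher in the TP53TG1 library of each pair, while NEAT1 and GAS5, of the same list, are lower in each. A general gain of short transcripts is argued against, since 53 protein-coding genes of at most 500 nt had a median only 0.12 above that of all genes (0.123, SD over genes 0.649). More carry-over of RNA without a poly(A) tail could raise the first 4 together. Against the control of the same number, from pair 1 to 3, summed snRNA was 5.62, 6.53 and 5.15 times, scaRNA 8.23, 1.41 and 5.07 times and snoRNA 3.96, 0.87 and 0.91 times, with rRNA 13.3 and 17.7 times in pairs 1 and 3 and at 0 in pair 2. Mitochondrial rRNA was 1.14, 1.16 and 0.73 times. The snRNA sum includes RN7SK, so it is not separate from the genes in question. In controls 1 to 3 RN7SK held 187, 36.5 and 41.1 of 685, 46.2 and 99.9 FPKM. In TP53TG1 replicates 1 to 3 it held 1293, 158 and 215 of 3855, 301 and 514 FPKM. The sum without it was not taken. Carry-over and an effect of TP53TG1 on these RNAs cannot be told apart, because snoRNAs may be lost by size and each group has its own libraries.

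The NF-kB list lies above the other genes with a preset correlation (adjusted p = 0.183 with an estimated correlation), with no member passing over all genes. The median of the NF-kB list lay at percentile 100 of 10000 random lists matched on transcript length and mean expression, which argues against length and level as its cause. PTPRC, the pan-leukocyte gene, reached at most 0.02 FPKM in the TP53TG1 libraries and 0.13 FPKM in the controls, which argues against RNA from leukocytes. The leukocyte list was nevertheless higher with no filter on low values (camera adjusted p = 0.000191). Most of its genes were near 0 there, where a negative median of all genes places them higher. A response of the cells to TP53TG1 stays open as a hypothesis, and so does a difference between the plasmid preparations or transfections, which was not tested.

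The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. As many changed genes as the real 1 came from 5 of the 10 splits, the highest of the others calling 116. That split set both libraries numbered 1 and TP53TG1 replicate 3 against the rest, so it points to a structure of the samples. For lists, 1 of the 10 splits, the real one, gave as many as 17, and the highest other gave 12. The 17 include the list that holds the transfected gene. Among the 4 splits that part all 3 pairs, with the replicate block, 1 gave as many as 192 genes, and the highest of the other 3, which exchange the libraries of 1 pair, gave 77. With median-of-ratios scaling added, the real split gave 7 genes and each of the other 3 gave 0.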
